A study of Saccharomyces cerevisiae with 26 samples.

How the data were processed

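RNA abundance was measured on Affymetrix yeast arrays in 26 samples of chemostat cultures of Saccharomyces cerevisiae, per the labels' protocols. The reference strain CEN.PK113-7D (MATa) and a strain lacking SFP1, which also has a mutated LEU2 complemented by the marker, were grown in glucose-limited aerobic chemostats at a dilution rate of 0.10 per h, 30 °C, pH 5.0 and 800 rpm. An anaerobic pulse of 200 mM glucose was then given, with samples at 5, 10, 30, 60 and 120 min. Steady state was sampled in 3 cultures per strain and each time point in 2, with replicates described as independent in the labels. The labels do not say whether the times were sampled from the same cultures.

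The deposited values are linear signal intensity per probe set, made by the authors with the Affymetrix GCOS software, per the submitters' processing notes. The GCOS version, the signal algorithm and the scaling step are not given in the sources used here. The intensity table itself shows that the arrays had been scaled: the 2% trimmed mean over all probe sets lay between 150.1 and 150.2 on every array. The values were therefore used as deposited, with no further scaling. No per-sample column of the table was left unused.

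The table holds 9335 probe sets, of which 60 are AFFX controls and were left out. The platform annotation names 1 gene for 6504 of the others, several genes for 328 and none for 2443. Symbols were updated through the Entrez identifier against the RefSeq gene table, in which all 5656 genes were found. For the 315 genes with over 1 probe set, the probe set with the highest mean log2 signal over all arrays was used. Signals under 12 were set to 12 (the floor) and log2 was taken, so a fold change against a group with an array at the floor is a lower bound and is written as at least that size. Genes above the floor on fewer than 2 arrays were left out (287 genes), which left 5369 genes for testing.

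Group means were fitted for all 12 groups together with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in R 4.3.3, with 14 residual degrees of freedom and 3.59 prior degrees of freedom. The comparisons were the deletion strain against the reference at steady state, each time point against steady state within a strain, and the strain by time interaction, that is, the deletion strain's change minus the reference strain's change. All tests were two-sided. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison, and moderated F-tests covered the 5 time points together. Standard errors are those of limma, and SDs are over the cultures of a group on the signal scale. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays limits the precision of every value.

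Before the data were examined, 29 gene lists, the rule for naming genes, the tests and most alternatives were fixed; the alternatives added later are named as such where they are used. The lists cover ribosome production, carbon and energy metabolism, storage, stress, oxygen-dependent genes, nutrient pathways, protein breakdown, cell cycle, mating and sporulation. Of these, 28 were tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, with p adjusted over the lists of all comparisons of a kind. The core histone list had fewer than 3 measured members and was not tested. Each camera test was repeated with the correlation estimated from the residuals, and list members were also adjusted over the list alone. Named genes are SFP1 and LEU2, the 12 called genes with the largest rise and the 12 with the largest fall at steady state whose arrays did not overlap between strains, and 3 of each per time point and strain by the same principle. The 10 most positive and 10 most negative interactions, up to 4 called members of each list described and a fixed set of marker genes complete them, 419 genes in all.

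The procedure was tested on simulated data built on the 5369 genes, with 100 genes changed per size. The changed genes were drawn from those whose mean log2 signal lay over 2 above the floor, with noise independent between genes. The shares recovered therefore do not cover genes of lower signal or correlated genes. For the steady state comparison 57 of 100 genes changed by 1 on the log2 scale and 95 of 100 changed by 2 were recovered, with 5 unchanged genes called. For the reference strain at 120 min 52 of 100 and 95 of 100 were recovered, with 11 unchanged genes called.

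Alternatives changed one choice at a time: quantile normalization, a common median, a floor of 48, no floor with log2 of the signal plus 1, no filter, only genes whose highest group mean exceeded a signal of 96, all probe sets, no intensity trend, stricter thresholds, the replicate number as a block (over the pulse arrays alone as an added alternative), the prefix of the array code in the labels' descriptions, only the groups compared, and each array left out in turn.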

Results

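The data are 26 arrays from 12 groups, 13 for the reference strain and 13 for the strain without SFP1. Each strain has 3 steady state cultures and 2 cultures at each of 5, 10, 30, 60 and 120 min after an anaerobic glucose pulse. A chemostat fixes the growth rate, so the steady state comparison asks which transcripts differ without Sfp1, an activator of ribosomal protein and ribosome biogenesis genes, when growth is equal. The strains differ at LEU2 as well, which the design does not separate from SFP1. The pulse asks how far the change to abundant glucose without oxygen needs it. The median signal per array lay between 22.7 and 49.0.

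Replicate arrays of 10 groups correlated at 0.970 to 0.993 across genes, which are not independent replicates. The other groups were the deletion strain at 10 and 30 min. The arrays labelled 10 min replicates 1 and 2 correlated at 0.805 and those labelled 30 min at 0.796. Instead, 10 min replicate 1 correlated at 0.978 with 30 min replicate 2, and 30 min replicate 1 at 0.922 with 10 min replicate 2. Values of these groups are given for the arrays as labelled. Counts over all genes and of some lists are given also without the arrays labelled 10 min replicate 2 and 30 min replicate 2 (the discordant arrays). This setting was chosen after seeing the data. Counts of the other lists use all arrays, and the discordant ones widen the spread shared by all groups. The inter-gene correlation estimated for camera also rests on the residuals of all arrays, so the discordant ones can raise it and its p. How far they did so was not tested list by list. The signal ratio of the 5' to the 3' probe set of actin, a sign of RNA integrity, lay between 0.697 and 0.923 on the reference arrays. It was 0.147, 0.00322 and 0.247 on the deletion arrays labelled steady state replicate 1, 30 min replicate 1 and 60 min replicate 1, and 0.598 to 0.968 on the other 10. The ratio of the middle to the 3' probe set was lowest on the deletion arrays labelled 30 min replicate 1 (0.176) and 10 min replicate 2 (0.207). Both deletion arrays at 60 min lay below every reference array in both ratios. Replicate 2 of that time, with 0.598 and 0.579, is among the other 10.

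**Figure D1:**
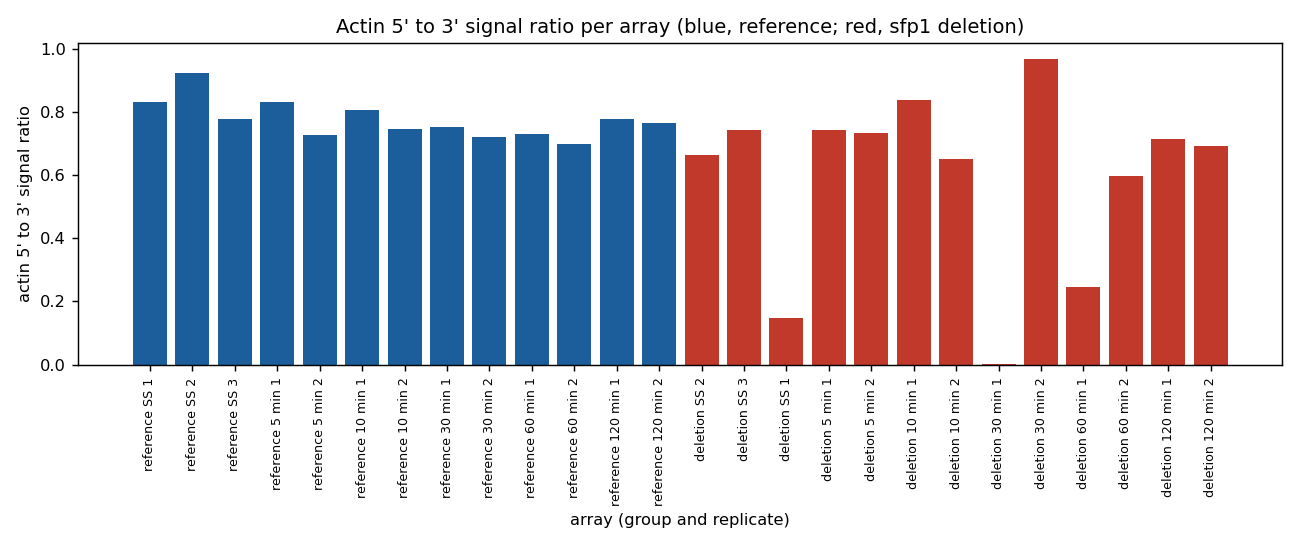
Ratio of the actin 5' probe set signal to the 3' probe set signal on each of the 26 arrays (bars, blue for the reference strain and red for the deletion strain; no unit). The reference arrays lie between 0.697 and 0.923, and 3 deletion arrays lie at 0.147, 0.00322 and 0.247.

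SFP1 (YLR403W) was at the floor on all 13 deletion arrays. In the reference strain its signal was 105.2 ± 9.17 (SD, n = 3) at steady state, 105.2 ± 3.46 (n = 2) at 5 min, 149.8 ± 6.22 at 10 min, 189.4 ± 22.1 at 30 min, 118.6 ± 7.85 at 60 min and 99.65 ± 3.46 at 120 min. At steady state it was at least 8.75-fold lower in the deletion strain (log2 change -3.13, SE 0.121, limma adjusted p = 1.1e-11). LEU2 (YCL018W), the leucine gene that is mutated in the deletion strain and complemented there by the Kluyveromyces lactis gene used as the marker, had a signal of 1275 ± 220 in the reference and 489.3 ± 15.9 in the deletion strain (2.58-fold lower, adjusted p = 0.0092). Whether its probe set also reads the marker gene was not checked, so the value may not be that of the yeast gene alone.

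At steady state the largest rise was in MF(ALPHA)1, which encodes the precursor of the alpha mating pheromone: 62.0 ± 8.60 in the reference and 674.8 ± 62.5 in the deletion strain (10.9-fold, log2 3.45, SE 0.231, n = 3 per strain, adjusted p = 5.3e-08). Other genes of mating rose with it, among them FUS1 and PRM1, which act in cell fusion (2.89-fold, adjusted p = 0.020, and 2.93-fold, adjusted p = 0.014). GPP2, a glycerol-3-phosphatase that has a close paralog, rose 4.77-fold. The hexose transporter gene HXT10 rose at least 3.53-fold from a signal near the floor, and HSP30, a stress protein of the plasma membrane, rose 3.49-fold. Among the genes that fell were RPA14, a subunit of RNA polymerase I (159.2 ± 17.6 to 49.47 ± 14.6, 3.30-fold), and GDH3, a glutamate dehydrogenase (3.41-fold). COX19, needed for cytochrome c oxidase assembly, fell at least 3.91-fold, SPC25 of the kinetochore 3.58-fold and RFU1, an inhibitor of ubiquitin recycling, 3.99-fold. Further genes with large rises were YOL162W (at least 4.29-fold), the maltose-type permease gene MPH2 (4.27-fold, not separable from its near-identical copy), CIS1 (3.19-fold), OSI1 (3.18-fold), the telomerase subunit gene EST3 (3.01-fold) and YER187W (2.84-fold). Large falls were also seen in EFM3 (3.77-fold), RSO55 (3.61-fold), COS10 (at least 3.56-fold, a member of a repeated gene family whose other probe sets differed in sign), the kinase gene YPK2 (at least 3.47-fold), CSS2 (3.29-fold) and the dynein gene PAC11 (at least 3.16-fold). The adjusted p of these genes ranged from 3.4e-05 for CSS2 to 0.049 for EFM3.

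**Figure D2:**
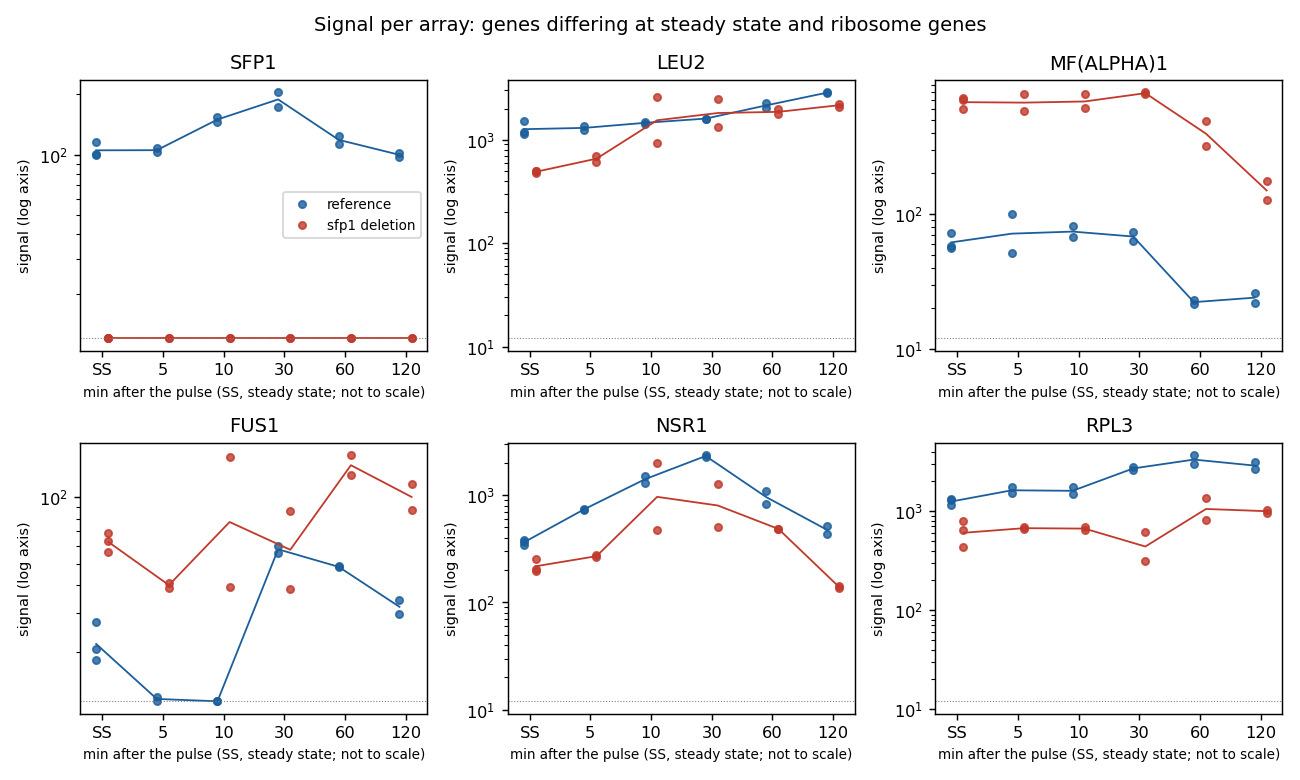
Signal per array (points, log axis, no unit) of SFP1, LEU2, MF(ALPHA)1, FUS1, NSR1 and RPL3 at steady state (SS) and 5 to 120 min after the pulse in the reference strain (blue) and the deletion strain (red), with lines through the geometric means and a dotted line at the floor of 12. SFP1 is at the floor in all 13 deletion arrays, and the deletion groups at 10 and 30 min include the arrays that differ from their replicates.

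By fixed list, the mating markers of a and alpha cells stood out: 4 of 9 rose, none fell and 9 were higher when adjusted over the list alone (median log2 0.98, camera adjusted p = 1.8e-07, adjusted p = 0.37 with an estimated correlation). Both alpha-specific and a-specific genes were among the 4, namely MF(ALPHA)1, ASG7 (log2 1.33), BAR1 (1.08) and the a-factor gene MFA2 (1.05). Of 32 proteasome genes 3 rose, none fell and 10 were higher when adjusted over the list alone (median 0.45, adjusted p = 2.6e-05, adjusted p = 0.49 with an estimated correlation). These were PRE9 at 0.67, RPN9 at 0.61 and PRE2 at 0.49. Without the discordant arrays more proteasome genes passed as higher and none as lower. Of 44 amino acid synthesis genes 7 fell, or 8 when adjusted over the list alone (median -0.12, adjusted p = 0.00011, adjusted p = 0.65 with an estimated correlation). Among them were the leucine and valine pathway genes LEU9 (-1.37) and ILV6 (-1.33), and the serine gene SER3 (-1.01). Without the discordant arrays amino acid synthesis genes passed in both directions, more of them lower than higher. The difference at LEU2 could bear on the leucine and valine genes. Of 26 translation factor genes 1 fell, TEF4 (-0.92), or 5 when adjusted over the list alone (median -0.23, adjusted p = 2.6e-05, adjusted p = 0.41 with an estimated correlation). In sulfur assimilation 1 of 18 fell, MET8 at -1.25, or 2 when adjusted over the list alone (median -0.16, adjusted p = 0.0092, adjusted p = 0.65 with an estimated correlation). In glycolysis 1 of 16 fell by either adjustment, over all genes or adjusted over the list alone, HXK2 from 1135 ± 92.2 to 570.4 ± 88.1 (median -0.14, adjusted p = 0.024, adjusted p = 0.65 with an estimated correlation). These small medians move with scaling: with a common median the amino acid, sulfur and glycolysis lists lay at -0.21, -0.25 and -0.24, and glycolysis at -0.08 after quantile normalization.

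Of the genes that Sfp1 is known to activate, few passed at this fixed growth rate with all arrays. Of 80 ribosomal protein genes 2 fell, RPL3 (1252 ± 90.3 to 622.0 ± 178, log2 -1.05, adjusted p = 0.019) and RPL22B (-1.24), and the same count was lower when adjusted over the list alone. The list's median was -0.03 as deposited, 0.02 after quantile normalization, where its sign turned, and -0.12 with a common median. The sign also turned when single arrays were left out, to 0.073 without the reference array labelled steady state replicate 2. Its camera adjusted p was 0.021, with adjusted p = 0.94 with an estimated correlation. Of 139 ribosome biogenesis genes LOC1 rose (0.78) and RRS1 fell (-0.79). None passed when adjusted over the list alone, and the list's median was -0.08, or -0.17 with a common median (adjusted p = 0.0020, adjusted p = 0.94 with an estimated correlation). Without the 2 discordant arrays 3 ribosomal protein genes were higher and 8 lower, and 12 and 26 of the ribosome biogenesis genes. The nucleolar marker genes NSR1 (-0.74, adjusted p = 0.25) and NOP1 (-1.15, adjusted p = 0.12), the small subunit gene RPS3 (-0.02, adjusted p = 1.0) and the cyclin gene CLN3 (-0.66, adjusted p = 0.27) did not pass. Their errors are pooled over all groups, the discordant arrays included, so not passing does not show that a gene was unchanged. For NSR1 the deletion signals (197.6 to 254.7) all lay below the reference signals (343.4 to 382.9). The remaining 20 lists had camera adjusted p of 0.052 or more. Paralogous ribosomal protein genes may share signal on these probe sets.

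In all, 308 genes passed at steady state, 199 higher and 109 lower in the deletion strain. Of these, 59 of the higher and 43 of the lower differed at least 2-fold. With a common median the split was 80 higher and 101 lower, and the median over all genes moved from 0.13 to 0.04. Without the 2 discordant arrays, which belong to other groups but widen the shared spread, the counts were 985 and 439. With all arrays but the deletion array labelled steady state replicate 1 they were 30 and 25.

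In the reference strain the first changes within 5 min were in a small set of genes. AQR1, a membrane transporter gene, went from the floor to 160.7 ± 0.283 (n = 2, at least 13.4-fold, log2 3.74, adjusted p = 1.8e-10). VID24, which targets gluconeogenic enzymes for breakdown, rose 13.2-fold. DIA1 rose by 3.45 on the log2 scale (adjusted p = 0.0033). ECM13 fell from 429.8 ± 36.9 to 24.95 ± 2.90 (log2 -4.11, adjusted p = 4.5e-10). YKR075C and the arrestin gene ROD1 fell 5.98-fold and 3.98-fold. At 10 min PHO84, the high-affinity phosphate transporter gene, went from the floor to 1119 ± 119 (at least 93.0-fold, adjusted p = 1.8e-10) and was back at 90.35 ± 7.99 at 30 min. HXT1, the low-affinity glucose transporter gene, went from the floor to 634.8 ± 14.6 at 10 min and 2048 ± 346 at 30 min (at least 169-fold, log2 7.41, adjusted p = 4.4e-08). YPL113C and YGR067C fell at 10 min, each 18.1-fold, the first of them as a lower bound.

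Ribosome production was the main group that rose. Of 139 ribosome biogenesis genes 76 rose at 10 min and 138 at 30 min (102 and 138 when adjusted over the list alone), with a median log2 change of 1.17 and 2.12 (camera adjusted p = 1.7e-32 and 1.8e-39, adjusted p = 0.27 and adjusted p = 0.26 with an estimated correlation). NSR1 went from 363.1 ± 19.8 at steady state to 2318 ± 56.6 at 30 min (6.39-fold, adjusted p = 2e-05) and 477.2 ± 57.2 at 120 min, where it no longer passed. The helicase gene HAS1 rose by 3.29 at 30 min. By 120 min 20 genes of the list were still higher (3 when adjusted over the list alone, median 0.53, adjusted p = 4.7e-10, adjusted p = 0.55 with an estimated correlation). These counts may be low, since the discordant arrays of the deletion strain widen the shared spread. Ribosomal protein genes rose later and stayed up: 76 of 80 at 30 min and 71 at 120 min (77 and 77 when adjusted over the list alone), with medians of 1.07 and 0.89 (adjusted p = 1.4e-22 and 7.7e-24, each with adjusted p = 0.27 with an estimated correlation). RPL3 reached 2700 ± 168 at 30 min and 3333 ± 479 at 60 min, against 1252 ± 90.3 at steady state. All 21 genes of RNA polymerases I and III rose at 30 min, also when adjusted over the list alone (median 1.71, adjusted p = 5.8e-11, adjusted p = 0.25 with an estimated correlation), RPA12 by 2.77. So did 22 of 26 translation factor genes, with 1 lower and the same counts when adjusted over the list alone (1.10, adjusted p = 5.4e-10, adjusted p = 0.13 with an estimated correlation).

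Nucleotide, amino acid and sulfur lists also rose. At 30 min 23 of 28 nucleotide synthesis genes rose and 2 fell (median 1.41, adjusted p = 3.5e-11, adjusted p = 0.25 with an estimated correlation), IMD4, which makes guanine nucleotides, by 3.91. Amino acid synthesis had 30 of 44 genes higher and 4 lower (1.02, adjusted p = 1.3e-10, adjusted p = 0.26 with an estimated correlation). Sulfur assimilation had 12 of 18 higher and none lower (1.25, adjusted p = 1.7e-06, adjusted p = 0.25 with an estimated correlation). In these 3 lists the counts were the same when adjusted over the list alone. Glycolysis rose in 11 of 16 genes and fell in 3, with the same counts when adjusted over the list alone (median 1.07, adjusted p = 0.0011, adjusted p = 0.29 with an estimated correlation). The fallers include HXK1 (-5.25), the hexokinase of low-glucose growth. Of 7 genes of alcoholic fermentation 4 rose and 2 fell, or 5 and 2 when adjusted over the list alone (1.18, adjusted p = 0.012, adjusted p = 0.21 with an estimated correlation). The pyruvate decarboxylase gene PDC5 was at 5.65 and its paralog PDC6 at -1.31. Outside the list the aldehyde dehydrogenase gene ALD6 was at -6.90, with 1 array at the floor, a value that the gene's other probe set did not share in sign.

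Respiratory and gluconeogenic transcripts were almost lost by 30 min. All 17 genes of gluconeogenesis and two-carbon metabolism fell (median -5.06, adjusted p = 0.0018, adjusted p = 0.56 with an estimated correlation). FBP1, the committing enzyme of gluconeogenesis, went from 803.9 ± 73.6 to 13.45 (59.6-fold), and the glyoxylate gene ICL1 fell 50.5-fold. All 16 genes of the tricarboxylic acid cycle fell (median -4.50, adjusted p = 0.0021, adjusted p = 0.58 with an estimated correlation), ACO1 67.6-fold. So did all 31 of the respiratory chain and ATP synthase (median -3.97, adjusted p = 3.5e-06, adjusted p = 0.55 with an estimated correlation). Cytochrome c, CYC1, went from 1576 ± 179 to 33.70 ± 5.37 (46.9-fold, adjusted p = 2e-06). NDI1, an NADH dehydrogenase gene, went from 1004 ± 102 to 12.90 ± 1.27, with 1 array at the floor. All 14 fatty acid oxidation genes fell (median -4.38, adjusted p = 0.0026, adjusted p = 0.55 with an estimated correlation), as did 16 of 17 glycogen and trehalose genes (-3.59, adjusted p = 0.00031, adjusted p = 0.50 with an estimated correlation). Losses also met 29 of 33 general stress genes (-3.45, adjusted p = 1.9e-05, adjusted p = 0.46 with an estimated correlation) and 63 of 65 mitochondrial ribosome genes (-1.39, adjusted p = 7e-07, adjusted p = 0.35 with an estimated correlation). All 32 proteasome genes fell (median -1.78, adjusted p = 1.8e-08, adjusted p = 0.25 with an estimated correlation), RPN12 by 2.76. In these lists no gene rose, and the counts adjusted over the list alone were the same except for the mitochondrial ribosome, where all 65 fell.

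Oxygen-dependent genes changed at several times. Of 24 ergosterol synthesis genes 6 were lower at 10 min by either adjustment, over all genes or adjusted over the list alone (median -0.37, adjusted p = 0.075, adjusted p = 0.55 with an estimated correlation). ANB1, the hypoxic form of translation factor eIF5A, went from 13.53 ± 2.66, with 1 of 3 arrays above the floor, to 2923 ± 200 at 30 min and 4337 ± 478 at 60 min (at least 323-fold). Its aerobic paralog HYP2 fell from 3898 ± 339 to 1101 ± 45.1. Part of either signal may come from the other gene. DAN1, a cell wall protein gene of anaerobic cells, went from the floor to 1035 ± 117 at 120 min (at least 86.0-fold, adjusted p = 5.8e-16). Of 19 hypoxic and anaerobic genes 13 rose and 2 fell at 120 min, with the same counts when adjusted over the list alone (median 1.70, camera adjusted p = 1.6e-09, adjusted p = 0.035 with an estimated correlation). HEM13 of heme synthesis rose 30.1-fold and the cell wall gene TIR1 25.2-fold. At 30 min 21 of the 24 ergosterol synthesis genes fell, none rose and the counts were the same when adjusted over the list alone (median -2.36, adjusted p = 5e-05, adjusted p = 0.26 with an estimated correlation). ERG5 went from 366.5 ± 19.4 to the floor (at least 30.5-fold).

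**Figure D3:**
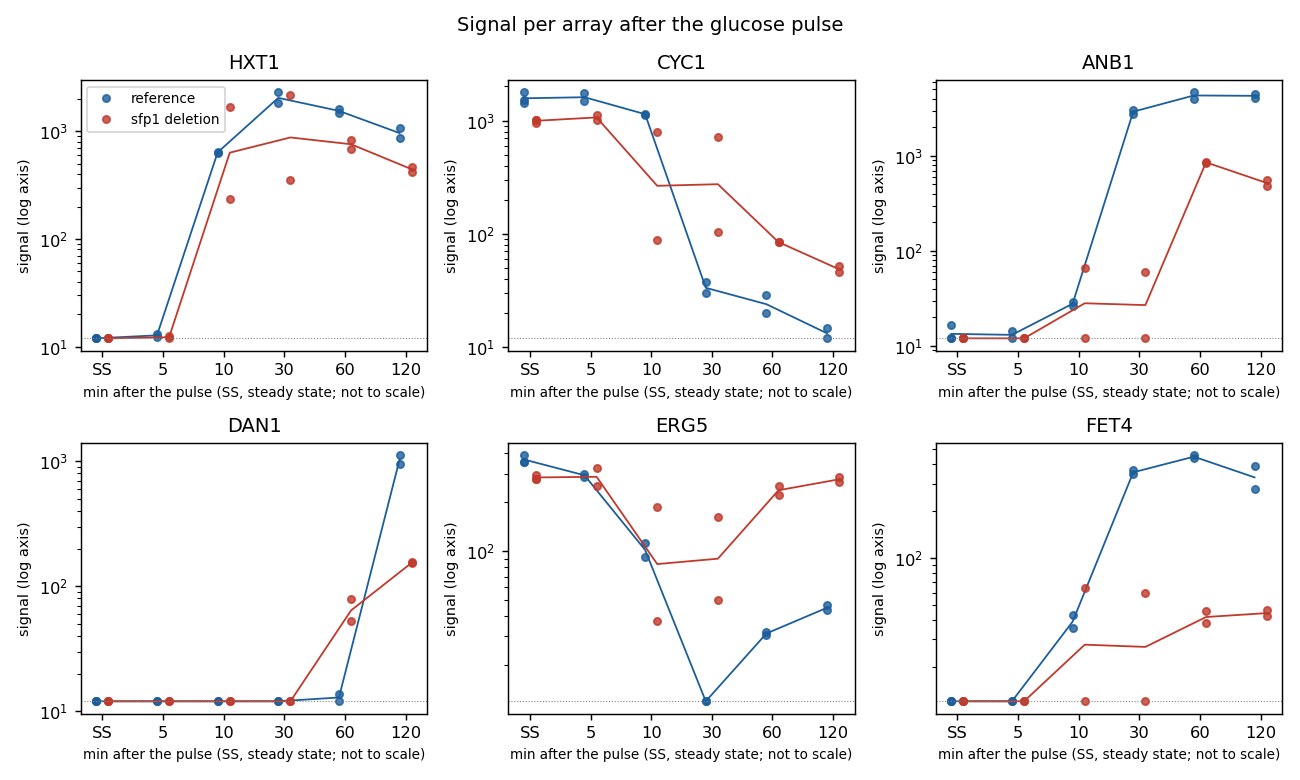
Signal per array (points, log axis, no unit) of HXT1, CYC1, ANB1, DAN1, ERG5 and FET4 at steady state (SS) and 5 to 120 min after the pulse, blue for the reference strain and red for the deletion strain, with lines through the geometric means and a dotted line at the floor of 12. ERG5 reached the floor at 30 min in the reference strain and was at 237.4 ± 20.6 at 60 min in the deletion strain, and the deletion groups at 10 and 30 min include the arrays that differ from their replicates.

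Over the time course 3875 genes (72.2%) passed the F-test in the reference strain. The counts of higher and lower genes were 27 and 75 at 5 min, 418 and 927 at 10 min, 1043 and 2601 at 30 min, 923 and 2069 at 60 min and 639 and 1529 at 120 min. These splits depend on scaling: at the same times they were 40 and 39, 527 and 582, 1692 and 1682, 1596 and 1420, and 1106 and 992 after quantile normalization. They were 39 and 31, 735 and 461, 2169 and 1438, 2056 and 1191, and 1441 and 881 with a common median. At 30 min the median over all genes was -0.53 as deposited, 0.003 after quantile normalization and 0.25 with a common median. Relative to it the ribosomal protein list lay at 1.60, 0.45 and 1.77 and the respiratory chain list at -3.44, -3.40 and -3.27. List medians at 30 min moved with scaling too. After quantile normalization and with a common median, glycolysis lay at 0.41 and 2.02, alcoholic fermentation at 0.59 and 2.13, and ribosomal proteins at 0.45 and 2.02. The mitochondrial ribosome lay at -0.67 and -0.44, the proteasome at -1.37 and -0.83 and ergosterol synthesis at -1.92 and -1.41. With a common median RNA polymerases I and III lay at 2.66, translation factors at 2.05, and nucleotide, amino acid and sulfur lists at 2.36, 1.97 and 2.21. At 120 min ribosomal proteins lay at 0.44 and 1.37 and ribosome biogenesis at 0.92 and 1.01, and at 10 min ergosterol synthesis had -0.04 with a common median. Without the 2 discordant arrays the F-test passed 4468 genes and the counts at the 5 times were 160 and 359, 815 and 1700, 1216 and 2847, 1183 and 2351, and 1020 and 2009.

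In the deletion strain the replicates were concordant at 5, 60 and 120 min. HXT1 went from the floor to 758.8 ± 98.4 at 60 min (n = 2, at least 63.0-fold, adjusted p = 1.7e-06) and 443.6 ± 33.4 at 120 min. ANB1 went from the floor to 855.0 ± 18.3 at 60 min (at least 71.2-fold, adjusted p = 2.7e-07) and 519.6 ± 48.5 at 120 min. INA1 rose by 4.61 and 4.58 at these times. RGI2, a gene of respiratory growth, fell 90.8-fold at 60 min and 123-fold at 120 min. SPG4 fell 139-fold and at least 167-fold, and MLS1, malate synthase, at least 85.0-fold at 60 min. CYC1 went from 994.3 ± 30.9 to 84.60 at 60 min and 48.85 ± 4.45 at 120 min. At 5 min AQR1 went from the floor to 90.55 ± 13.5 (adjusted p = 1.3e-08), DIA1 rose by 2.61, and ECM13 (-3.30), YKR075C (-2.40) and YGR035C (at least 3.26-fold) fell. For the arrays labelled 10 and 30 min, AQR1 rose by at least 5.29 and YDR222W by 4.67 at 30 min, while ECM13 fell by 4.10 at 10 min and SFC1, a mitochondrial carrier gene, at least 24.7-fold at 30 min.

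By list at 60 min, 89 of 139 ribosome biogenesis genes rose and none fell (107 when adjusted over the list alone; median 1.14, adjusted p = 2e-16, adjusted p = 0.50 with an estimated correlation), KRE33 by 2.13. Of 80 ribosomal protein genes 23 rose and none fell (13 when adjusted over the list alone; median 0.53, adjusted p = 8.8e-09, adjusted p = 0.57 with an estimated correlation). After quantile normalization and with a common median the 60 min median was 0.265 and 0.815. The counts of this list at 60 and 120 min may be low, since the discordant arrays, in none of the groups compared, widen the shared spread. At 120 min none passed, over all genes or over the list alone (median 0.21, or 0.11 after quantile normalization, adjusted p = 0.0091, adjusted p = 0.82 with an estimated correlation). All 17 gluconeogenic and two-carbon genes fell at 60 min, also over the list alone (median -5.63, adjusted p = 3.1e-09, adjusted p = 0.40 with an estimated correlation). So did 30 of 31 respiratory chain genes, or 31 when adjusted over the list alone (-2.65, adjusted p = 2.8e-10, adjusted p = 0.50 with an estimated correlation). Of 33 stress genes 31 fell by either adjustment, over all genes or adjusted over the list alone (-3.24, adjusted p = 1.3e-15, adjusted p = 0.31 with an estimated correlation). The hypoxic list had 14 genes higher and 1 lower of 19 at 120 min, or 14 and 2 when adjusted over the list alone (1.49, adjusted p = 1.2e-09, adjusted p = 0.029 with an estimated correlation). TIR1 was 21.8-fold higher and DAN1 at 154.1 ± 1.56, at least 12.8-fold above the floor.

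Chaperone genes rose in this strain on the arrays labelled 10 and 30 min. These groups hold the discordant arrays and those with the lowest actin middle to 3' ratios (10 min replicate 2 at 0.207, 30 min replicate 1 at 0.176). Of 15 cytosolic and mitochondrial chaperone genes 11 and 12 rose and none fell, with 12 and 12 when adjusted over the list alone (medians 1.01 and 1.00, adjusted p = 2.8e-10 and 2.1e-11, adjusted p = 0.061 and adjusted p = 0.057 with an estimated correlation). HSP82 rose 2.26-fold at 10 min and HSP104 1.78-fold at 30 min. Proteasome genes changed little: 3 of 32 fell at 60 min, or 1 when adjusted over the list alone, and the median was -0.18 as deposited and 0.11 with a common median (adjusted p = 0.33). Of 24 ergosterol genes 4 rose and 5 fell at 60 min, or 3 and 5 when adjusted over the list alone (median -0.07, 0.22 with a common median, adjusted p = 0.91).

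**Figure D4:**
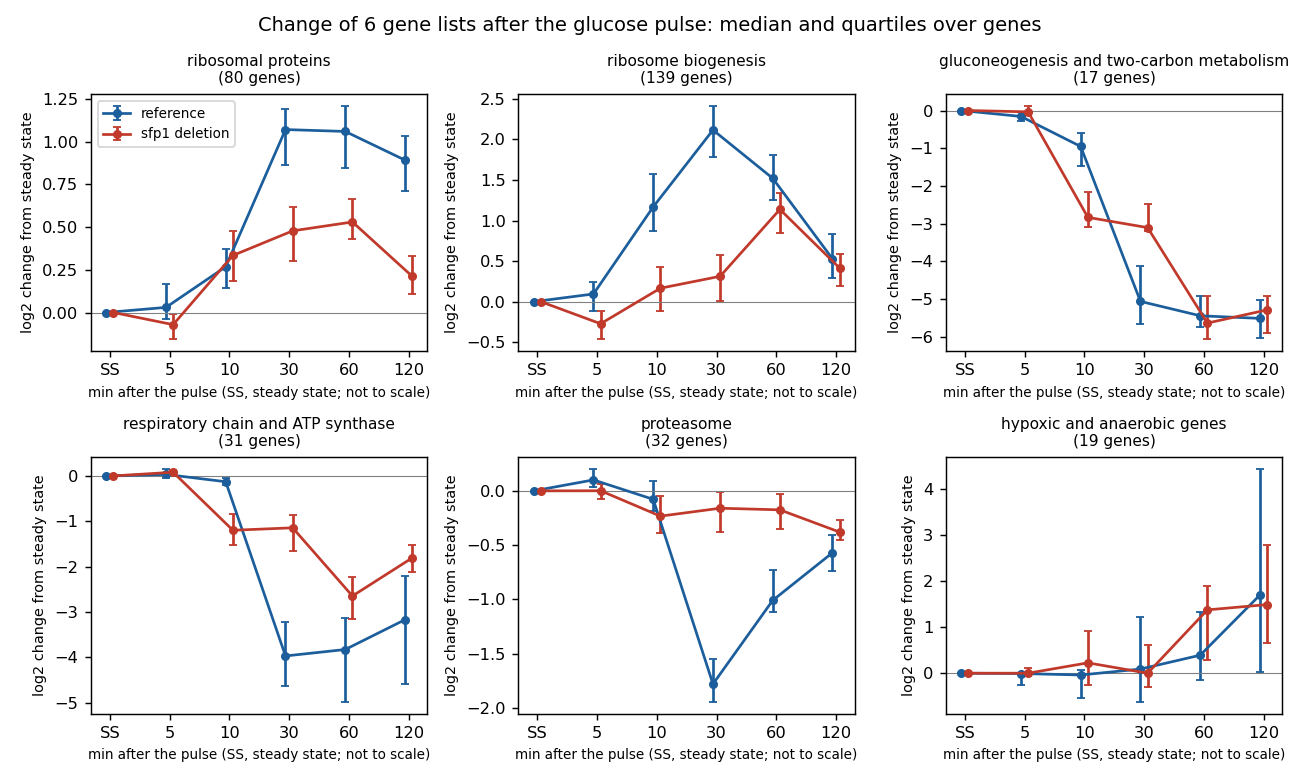
Log2 change from steady state (SS) of 6 gene lists at 5 to 120 min after the pulse, as the median over the list's genes (points) with quartiles over genes (bars), blue for the reference strain and red for the deletion strain. Ribosomal protein genes reached a median of 0.89 at 120 min in the reference and 0.21 in the deletion strain, as deposited; the deletion groups at 10 and 30 min include the arrays that differ from their replicates.

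The F-test over time passed 3066 genes (57.1%) in the deletion strain. Higher and lower genes numbered 15 and 33 at 5 min, 362 and 1390 at 10 min, 372 and 1254 at 30 min, 867 and 1334 at 60 min and 462 and 686 at 120 min. After quantile normalization they were 23 and 17, 581 and 867, 568 and 723, 1297 and 1194, and 605 and 752. With a common median they were 21 and 17, 779 and 559, 952 and 500, 1526 and 1025, and 458 and 671. At 60 min the median over all genes was 0.00 as deposited, 0.14 and 0.24 in turn. Without the 2 discordant arrays the F-test passed 4244 genes and the counts were 98 and 268, 341 and 1339, 1110 and 1937, 1446 and 1681, and 1071 and 1194.

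The interaction asks which responses differed between the strains. Both deletion arrays at 60 min had actin 5' to 3' ratios (0.247 and 0.598) and middle to 3' ratios (0.560 and 0.579) below every reference array. No setting left out both, so at 60 min an effect of RNA integrity cannot be told apart from one of the strain. Ergosterol genes fell less in the deletion strain: at 60 min 9 of 24 had a positive interaction and none a negative one, or 18 when adjusted over the list alone (median log2 1.31, adjusted p = 3.5e-10, adjusted p = 0.22 with an estimated correlation). At 120 min 5 were positive, or 11 over the list alone (0.99, adjusted p = 2.2e-08, adjusted p = 0.23 with an estimated correlation). ERG5 had an interaction of 3.29 at 60 min (adjusted p = 0.0081) and ERG3 of 1.88. Proteasome genes likewise had 7 of 32 positive and none negative at 60 min, or 20 when adjusted over the list alone (0.75, adjusted p = 5.1e-10, adjusted p = 0.23 with an estimated correlation), among them PRE3 (1.29) and RPT2 (1.28). Chaperones were positive in 4 of 15 at 60 min, or 9 when adjusted over the list alone (0.76, adjusted p = 0.00030, adjusted p = 0.27 with an estimated correlation). Outside this list the small heat shock gene HSP26 had 3.59 at 120 min (adjusted p = 2.3e-08), with 28.90 ± 2.83 in the reference and 362.0 ± 27.6 in the deletion strain, and within it HSP104 had 2.14 at 60 min. All these medians stayed positive under both other scalings but were smaller with a common median, where the proteasome and chaperones at 60 min lay at 0.35 and 0.36 and ergosterol synthesis at 120 min at 0.55.

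Among single genes, YRO2, which encodes a membrane protein related to Hsp30, had an interaction of 4.07 at 60 min (adjusted p = 8.9e-06), with 26.05 ± 4.45 in the reference and 452.4 ± 13.6 in the deletion strain. PLN1, a lipid droplet protein gene, had 4.65 at 120 min (adjusted p = 0.0019): it went from 1634 ± 203 to 17.20 ± 4.53 in the reference and from 1277 ± 22.9 to 333.0 ± 28.8 in the deletion strain. The anaerobic gene DAN1 was earlier but weaker in the deletion strain, with at least 2.32 at 60 min (adjusted p = 6.2e-06), where a reference array was at the floor, and -2.74 at 120 min (adjusted p = 2.1e-07). The iron transporter gene FET4 had -3.42 at 60 min (adjusted p = 0.015), the sulfate permease gene SUL1 -2.79 at 120 min. DAN1 and FET4 were at the floor in both strains at steady state, so their values compare the levels after the pulse alone. UBI4 (polyubiquitin) had 2.49 and COX12 of cytochrome c oxidase 2.67 at 60 min. For ANB1 the interaction was -2.18 at 60 min (adjusted p = 0.13) and -2.89 at 120 min (adjusted p = 0.065), so it did not pass there. The signals were 842.1 and 868 in the deletion strain against 3999 and 4674.6 in the reference at 60 min. At 120 min they were 485.3 and 553.9 against 4086.6 and 4493.5. The error of the interaction includes the discordant arrays, and the level after the pulse was not itself tested.

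Ribosomal protein genes rose less in the deletion strain as a list at the preset correlation, while calls of single genes depended on the discordant arrays. At 120 min the median interaction was -0.69 as deposited, -0.30 after quantile normalization and -1.13 with a common median (as deposited, camera adjusted p = 1.7e-34, adjusted p = 0.25 with an estimated correlation). No member passed over all genes or adjusted over the list alone, and without the 2 discordant arrays 53 of 80 passed, all negative. Averaged over the 5 times the list had a median of -0.39 (-0.27 after quantile normalization, -0.65 with a common median) with 1 of 80 negative and none adjusted over the list alone (adjusted p = 2.4e-15, adjusted p = 0.37 with an estimated correlation). Ribosome biogenesis had -0.78 with 2 of 139 negative, LOC1 and RRP9, and 1 adjusted over the list alone (adjusted p = 1.3e-30, adjusted p = 0.25 with an estimated correlation). RNA polymerases I and III had -0.68 with 3 of 21 negative, RPA43 and RPA34 among them, and 6 adjusted over the list alone (adjusted p = 1.4e-10, adjusted p = 0.23 with an estimated correlation).

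At 30 min the interaction rests on the pair of discordant arrays, and its largest values came from there. ANB1 had -6.61 (-5.45 without the 2 arrays), FET4 -3.73 (-2.57), ECM1 of ribosome export -3.73 (-3.41) and IMD4 -3.52 (-2.36). The hexose transporter gene HXT5 had 5.30 (3.53), the glutaredoxin gene GRX2, at the floor in the reference, 4.88 (3.44), the peroxiredoxin gene AHP1 4.11 (3.89) and HSP26 4.15 (4.22). In the lists 104 of 139 ribosome biogenesis genes were negative and 29 of 32 proteasome genes positive there with all arrays. Without the 2 arrays the deletion group at 30 min holds replicate 1 alone. That array had the lowest actin 5' to 3' ratio of all (0.00322), so the values in brackets are not an independent check.

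The interaction F-test passed 1124 genes (20.9%). No gene passed at 5 min (limma; 140 had an unadjusted p under 0.05), and positive and negative calls numbered 24 and 51 at 10 min, 1131 and 486 at 30 min, 165 and 41 at 60 min and 87 and 15 at 120 min. These splits were 24 and 31, 621 and 580, 74 and 46, and 37 and 24 after quantile normalization, and 28 and 34, 625 and 976, 61 and 87, and 24 and 41 with a common median. The median over all genes at 60 min was 0.26 as deposited, 0.00 and -0.08 in turn. Relative to it the ergosterol list lay at 1.05, 1.11 and 0.98. Of the ranges that follow, the upper ends at 10 and 30 min came without deletion 10 min replicate 1 and 30 min replicate 1. Each removal left a discordant array alone in its group, so these ends do not measure ordinary spread. Leaving out single arrays moved the interaction counts to between 719 and 2504 in the F-test, 2 and 1018 at 10 min, 1029 and 2616 at 30 min, 85 and 425 at 60 min and 20 and 256 at 120 min. Without the 2 discordant arrays the F-test passed 2855 genes, with 28 at 5 min and 328 and 634, 1497 and 620, 974 and 282, and 819 and 233 at the later times. Across the 5369 genes, which are not independent replicates, the strains' changes correlated at r = 0.524 (rho = 0.367) at 5 min, 0.634 (0.586) at 10 min, 0.743 (0.711) at 30 min, 0.908 (0.870) at 60 min and 0.873 (0.784) at 120 min, with no arrays shared between them. Of the genes called in the reference, 94.1%, 89.7%, 85.9%, 93.5% and 92.3% had the same sign in the deletion strain at the 5 times, with slopes of 0.634, 0.683, 0.411, 0.759 and 0.682. The correlations and slopes at 10 and 30 min average arrays that differ from their replicates. Choosing genes by their reference calls can by itself lower a slope, so the slopes alone do not measure a weaker response.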

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

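The tests of exchanged labels, of culture progress, of degraded RNA and of alpha cells were chosen after their results were seen, as were the settings without the discordant arrays and without the low-actin arrays.

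The arrays labelled deletion 10 min replicate 2 and 30 min replicate 2 stood far from the other array of their group. Each correlated better with the remaining array of the other's group than with its own, by at least 0.117, where the largest such gain of the 22 other arrays was 0.00244; an exchange of these labels is consistent with this. A culture 2 that was further along than culture 1 is argued against, since on the axis of the reference 30 min response the array labelled 30 min 2 lay behind that labelled 10 min 2 (difference -0.484, against a largest replicate difference of 0.0687 at 5, 60 and 120 min). Degraded RNA is argued against for the array labelled 30 min 2 itself, whose actin middle to 3' ratio was 0.848 (lowest reference array 0.624). The arrays labelled 10 min 2 (0.207) and 30 min 1 (0.176), which resemble each other, share a low ratio, so degradation of that pair stays open beside an exchange. It cannot by itself account for the likeness of the arrays labelled 10 min 1 and 30 min 2. These had actin middle to 3' ratios of 0.872 and 0.848, correlated at 0.978 and lay at 0.14 and 0.166 on the same axis. The arrays labelled 10 min 2 and 30 min 2 have a code prefix (MA) that only deletion 60 min replicate 1 shares. Beyond culture progress no biological explanation was tested, and no label was changed.

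The smaller rise of ribosomal protein genes in the deletion strain at 120 min had a median interaction of -0.69 (camera p = 0.028 with an estimated correlation, unadjusted). Of the 5 doubted arrays only deletion steady state 1, a low-actin one, enters the means compared here, and it is argued against as the source: without the 5 the median was -0.71 (camera p = 0.0018 with an estimated correlation). Scaling cannot be told apart from an effect of the strain, since the median nearest 0 over the other scalings was -0.297 (camera p = 0.14 with an estimated correlation). A weaker response of all genes likewise cannot be told apart from it: after the reference change was multiplied by the slope of 0.686 over 2097 called genes outside the list, the median difference was -0.41 (camera p = 0.087 with an estimated correlation). The slope was taken over genes chosen by their reference calls, which can lower it and so move this difference toward 0. The scaling and slope tests used all arrays, the discordant ones included, and were not repeated without them. Loss of Sfp1 as a direct activator of these genes stays open and was not tested.

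The mating genes that were higher in the deletion strain at steady state had a median of 0.98 over 9 markers. Alpha cells in place of a cells are argued against, because the a-cell genes had a median of 1.014 and 3 of them were called higher. The low-actin steady state array is argued against as the source, since without it MF(ALPHA)1 was still higher by 3.398 on the log2 scale and the marker list had a camera p of 0.0093 with an estimated correlation, not adjusted over lists. A small share of alpha cells cannot be told apart from a change within a cells, since the alpha-specific genes STE3 (0.572) and SAG1 (0.635) lay above 0 but did not pass. A different state of the mating pathway without Sfp1 stays open, since 16 further pheromone-induced genes had a median of 0.644 but missed the threshold as a list (camera p = 0.065 with an estimated correlation). That list was written after the data were seen, and its test used all arrays, the discordant ones included.

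For the 308 genes called at steady state, the 6 arrays allow 10 splits, too few for a share under 0.05. Only 1 split, the real one, reached 308, and the highest other gave 1. Every other split mixes the strains and so puts their difference into the spread. Few calls were therefore likely there from the outset, and the counts do not measure false calls.

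The responses differed between the strains by the interaction test in 1124 genes over the time course, in 75 at 10 min, 1617 at 30 min, 206 at 60 min and 102 at 120 min. Averaged over time the interaction differed from that of other genes, at the preset correlation, for ribosomal proteins (-0.386), ribosome biogenesis (-0.783), RNA polymerases I and III (-0.678), translation factors (-0.465), nucleotide synthesis (-0.380), amino acid synthesis (-0.107) and sulfur assimilation (-0.099). It was positive for the respiratory chain (0.743), general stress genes (0.758), chaperones (0.697), ergosterol synthesis (0.812), the proteasome (0.449) and G1/S genes (0.530); with an estimated correlation the adjusted p of these 13 lists lay between 0.11 and 0.70. Of single genes, the interaction at 30 min was 5.301 for HXT5, 4.881 for GRX2, 4.442 for HXK1, 4.175 for BTN2, 4.146 for HSP26, 4.114 for AHP1, 4.082 for CYB2 and 4.037 for PNC1. It was -6.609 for ANB1, -3.732 for ECM1, -3.727 for FET4, -3.567 for OPT1, -3.564 for UTP30, -3.520 for IMD4, -3.386 for KRR1, -3.327 for HXT4 and -3.237 for GFD2 at that time, which holds both discordant and low-actin arrays. GRX2 and CYB2 were at the floor there in the reference, and ANB1, FET4 and OPT1 at or near it at steady state, which leaves the size of these values open. At other times it was -3.782 for NOG2 at 10 min, 4.065 for YRO2 at 60 min and 4.647 for PLN1 at 120 min. Of these times, 10 min holds the other discordant array. Both deletion arrays at 60 min lie below the reference arrays in the actin ratios, and replicate 1 there is a low-actin one. In control probe sets outside the comparisons, the actin 5' to 3' ratio was 0.147, 0.00322 and 0.247 on the deletion arrays labelled steady state 1, 30 min 1 and 60 min 1, below the lowest reference array by over 2-fold. Of 1312 tested probe sets that name no gene or several genes, 106 were called at steady state.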

How the results depend on the processing

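The settings without the 3 low-actin arrays, without the 2 discordant arrays, without these 5 and with a block over the pulse arrays alone were added after seeing the data. The reference counts over the time course and at 30 and 60 min moved by over 1.5 times under no setting. Under eBayes without the intensity trend the 24 results compared kept their call or a count within 1.5 times, and the 4 list results compared with the mean in place of the median kept their direction. Other lists were not compared under the mean. Of the 105 named gene effects tested under the settings none reversed. Over effects and planned settings the call was lost in 156 comparisons and unchanged in 2994. Under the added settings it was lost in 5 and unchanged in 287. Low signals limit what can be seen, since 287 genes were at the floor on all arrays or all but 1. A lower p or a required fold lowers counts by construction; for the other changes the cause was not tested. Where a group is left with 1 array, it is assumed to vary like the other groups.

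Scaling, floor and filter moved these counts. Quantile normalization gave 677 genes with a strain by time interaction. For genes with a strain by time interaction at 5 min it gave 1, for genes with a strain by time interaction at 60 min 120, and for genes with a strain by time interaction at 120 min 61. For the ribosomal proteins list at steady state the median reversed to 0.019. A common median gave 80 steady state genes higher in the sfp1 deletion and 65 interactions at 120 min. The raised floor gave 313 higher at steady state, and for sfp1 deletion genes changed at 5 min 122. It gave 1, 181, 316 and 212 interactions at 5, 10, 60 and 120 min, the second being genes with a strain by time interaction at 10 min. With no floor, reference strain genes changed at 5 min were 52, and with no filter there were 5 interactions at 5 min. The stricter filter gave 132 higher, and 66 steady state genes lower in the sfp1 deletion. It gave 35 and 759 in the reference at 5 and 10 min, the latter being reference strain genes changed at 10 min, 21 in the deletion strain at 5 min and 63 interactions at 120 min. All probe sets gave 302 higher and 203 lower at steady state, and the ribosomal protein median there (-0.038) no longer passed. An estimated correlation in camera ended the calls of the ribosomal protein and ribosome biogenesis lists at steady state (-0.026 and -0.079) and averaged over the interactions (-0.386 and -0.783).

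The labels do not say whether equal replicate numbers mark a shared culture, and the values do not settle it. Over 15 pairs of time points per strain, the deviations of equally numbered cultures correlated at -0.251 to 0.272 in the reference (8 over 0.1) and -0.719 to 0.334 in the deletion strain (4 over 0.1). Among the reference pulse arrays all 10 pairs were positive (0.0697 to 0.272), while those with steady state ran from -0.251 to 0.127. With the replicate block as a random effect (consensus correlation -0.0368), genes with a strain by time interaction at 10 min were 49. With the replicate block over the pulse arrays alone, no count moved by over 1.5 times. Its consensus correlation was -0.0595 over all pulse arrays, 0.148 in the reference, -0.112 in the deletion strain and 0.048 there without the 2 discordant arrays. A correlation as small as that over all pulse arrays can move counts little, so this setting cannot decide whether cultures were shared. With the replicate block as a fixed effect, reference strain genes changed at 5 min were 56 and sfp1 deletion genes changed at 5 min 31. Genes with a strain by time interaction were 685 in the F-test and 1, 17, 927, 98 and 39 at the 5 times, against 1124 and 0, 75, 1617, 206 and 102 without it. The steady state comparison could not be fitted with a fixed block.

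Leaving out several arrays raised most counts. Without the 3 arrays with an MA code, steady state genes higher in the sfp1 deletion were 1144 and steady state genes lower in the sfp1 deletion 518. There were 687 reference strain genes changed at 5 min and 2666 reference strain genes changed at 10 min. There were 482 sfp1 deletion genes changed at 5 min, 3208 sfp1 deletion genes changed at 30 min and 2478 sfp1 deletion genes changed at 120 min. The interaction F-test gave 3014 genes with a strain by time interaction, with 59 at 5 min. There were 1115 genes with a strain by time interaction at 10 min, 871 genes with a strain by time interaction at 60 min and 1319 genes with a strain by time interaction at 120 min. The code as a covariate gave 1 interaction at 5 min. Without the 3 low-actin arrays the reference had 209 at 5 min and the deletion strain 990 at 30 min. The interaction F-test then gave 2366, with 2 and 138 at 5 and 10 min, 289 at 120 min and 2592 genes with a strain by time interaction at 30 min. That setting leaves a discordant array alone in the deletion group at 30 min. The ribosomal protein median at steady state (-0.015) no longer passed. Without the 2 discordant arrays, steady state gave 985 and 439, the reference 519 and 2515 at 5 and 10 min, and the deletion strain 366, 3047 and 2265 at 5, 30 and 120 min. The interaction F-test gave 2855, with 28, 962, 1256 and 1052 at 5, 10, 60 and 120 min. Without all 5, steady state gave 671 and 366, the reference 757 and 2735 at 5 and 10 min, and the deletion strain 286 and 2319 at 5 and 120 min. The interaction F-test gave 2100, with 49, 1117, 872 and 1356 at 5, 10, 60 and 120 min, and the ribosomal protein median at steady state (-0.015) no longer passed. Without the 2 arrays the median residual SD was 0.202 on the log2 scale, against 0.296 with all arrays.

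With only the arrays of the groups compared, there were 467 steady state genes higher in the sfp1 deletion and 196 steady state genes lower in the sfp1 deletion. There were 593 reference strain genes changed at 5 min and 2555 reference strain genes changed at 10 min. There were 1034 sfp1 deletion genes changed over the time course. By time these were 13 sfp1 deletion genes changed at 5 min, 658 sfp1 deletion genes changed at 10 min, 577 sfp1 deletion genes changed at 30 min, 1159 sfp1 deletion genes changed at 60 min and 415 sfp1 deletion genes changed at 120 min. With at least 2-fold required, steady state gave 59 and 43, the reference 66 and 781 at 5 and 10 min, and 1315 reference strain genes changed at 120 min. The deletion strain gave 1947 in the F-test and 1039, 948, 1377 and 687 from 10 min on. At an adjusted p under 0.01, steady state gave 31 and 19, and the reference 49, 762 and 1427 at 5, 10 and 120 min. The deletion strain gave 1905 in the F-test and 24, 918, 870, 1402 and 631 at the 5 times. The F-test gave 496 genes with a strain by time interaction, with 7 at 10 min, 715 genes with a strain by time interaction at 30 min, and 85 and 29 at 60 and 120 min.

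Leaving out each array in turn gave 30 to 391 higher and 25 to 219 lower genes at steady state. The reference F-test ranged from 3555 to 4189 and its time points from 35 to 171, 646 to 1753, 3177 to 3832, 2344 to 3224 and 1367 to 2488. For the deletion strain the F-test ranged from 2621 to 3907 and the time points from 15 to 98, 831 to 2575, 1191 to 2547, 1583 to 2610 and 537 to 1563. The interaction F-test ranged from 719 to 2504 and the time points from 0 to 7, 2 to 1018, 1029 to 2616, 85 to 425 and 20 to 256. The ribosomal protein median ranged from -0.07 to 0.073 at steady state and -0.461 to -0.291 averaged over the interactions. The ribosome biogenesis median ranged from -0.129 to -0.044 and from -0.916 to -0.646.

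Single arrays moved counts by over 1.5 times as follows. For steady state genes higher in the sfp1 deletion and steady state genes lower in the sfp1 deletion, removal of reference steady state 1 gave 107 and 59, with 3 and 28 interactions at 5 and 10 min. Reference steady state 2 gave 76 and 35, with 61 reference strain genes changed at 5 min, 35 interactions at 10 min and a ribosomal protein median of 0.073. Reference steady state 3 gave 82 and 43, with 22 and 65 interactions at 10 and 120 min. Deletion steady state 1 gave 30 and 25, with 25 sfp1 deletion genes changed at 5 min, 26 interactions at 10 min and a ribosomal protein median of -0.015. Deletion steady state 2 gave 47 and 25, with 27 deletion genes at 5 min and 25, 132 and 54 interactions at 10, 60 and 120 min. Deletion steady state 3 gave 7 interactions at 5 min and a ribosomal protein median of 0.007. Either reference 5 min array gave 41 or 35 reference genes there and 43 interactions at 10 min. Either reference 10 min array gave 697 or 646 reference strain genes changed at 10 min and 16 or 2 interactions there. Reference 30 min 1 gave 719 in the interaction F-test and 1075 genes with a strain by time interaction at 30 min, and reference 30 min 2 gave 1029 of the latter. Either reference 60 min array gave 37 interactions at 10 min and 97 or 85 at 60 min. Either reference 120 min array gave 1367 or 1433 reference strain genes changed at 120 min, 36 interactions at 10 min and 25 or 39 at 120 min.

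Of the deletion pulse arrays, either 5 min array gave 131 steady state genes higher in the sfp1 deletion, 15 or 18 sfp1 deletion genes changed at 5 min and 37 interactions at 10 min. The second also gave 4 interactions at 5 min. Removal of 10 min 1 gave 340 higher and 172 steady state genes lower in the sfp1 deletion, 171 reference strain genes changed at 5 min and 98 deletion genes at 5 min. The interaction F-test then gave 2455, with 4 genes with a strain by time interaction at 5 min, 1018 genes with a strain by time interaction at 10 min, 410 genes with a strain by time interaction at 60 min and 226 genes with a strain by time interaction at 120 min. Removal of 10 min 2 gave 341 and 172, 171 and 98, and 831 sfp1 deletion genes changed at 10 min. The F-test gave 1698, with 4, 277, 410 and 226 interactions at the same times. Removal of 30 min 1 gave 383 and 215, 158 and 92, and 2504 in the F-test. At 10, 60 and 120 min there were 235, 424 and 256 interactions, and 2616 genes with a strain by time interaction at 30 min. Removal of 30 min 2 gave 391 and 219, 158 and 89, 2547 sfp1 deletion genes changed at 30 min, and 235, 425 and 245 interactions at 10, 60 and 120 min. Either 60 min array gave 2 interactions at 5 min and 94 or 373 at 60 min. Either 120 min array gave 537 or 595 sfp1 deletion genes changed at 120 min, 37 interactions at 10 min and 20 or 55 at 120 min.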

Other observations

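The test of Leu3 target genes was chosen after the result was seen.

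Cell cycle genes of the G1/S transition fell in both strains. In the reference strain 12 of 17 fell at 10 min and none rose, or 13 when adjusted over the list alone (median -0.95, camera adjusted p = 1.6e-05, adjusted p = 0.25 with an estimated correlation). CDC45, a replication factor gene, fell 4.12-fold, and the transcription factor gene SWI4 went from 41.40 ± 9.56 to the floor (at least 3.39-fold lower). At 30 min 15 were lower by either adjustment (-1.98), at 60 min 14, or 15 over the list alone (-1.64), and at 120 min 4, or 2 over the list alone, with none higher at any of these times. In the deletion strain 13 of 17 fell on the arrays labelled 10 min and none rose, also over the list alone (-1.12, adjusted p = 0.00015, adjusted p = 0.31 with an estimated correlation). At 120 min 4 of 17 were higher and 1 lower there, or 6 and 1 when adjusted over the list alone (0.48, adjusted p = 0.0022, adjusted p = 0.41 with an estimated correlation), with the S-phase cyclin gene CLB6 3.62-fold higher. The interaction at 60 min was positive in 5 and negative in none, or 13 when adjusted over the list alone (1.06, adjusted p = 8.6e-06, adjusted p = 0.23 with an estimated correlation), with PCL1 at 1.91 and RFA1 at 1.79. With a common median the list's reference medians at 10, 30 and 60 min were -0.62, -1.27 and -0.94, that of the deletion strain at 10 min -0.71, and the interaction 0.655.

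Of 8 glycerol genes 2 rose within 5 min in the reference strain and none fell, also when adjusted over the list alone (median 0.54, adjusted p = 0.00011, adjusted p = 0.13 with an estimated correlation): the glycerol-3-phosphatase paralogs GPP2, 9.65-fold, and GPP1, 3.40-fold. GPP2 reached 1463 ± 23.6 at 30 min and lay at 33.00 ± 0.990 at 60 min, below its steady state signal of 49.30 ± 5.75. Hexose transporter genes went both ways at 30 min, 3 of 12 up and 5 down by either adjustment (median -0.06, adjusted p = 0.51), with HXT3 15.4-fold higher and HXT5 60.4-fold and HXT7 9.54-fold lower, the last not separable from HXT6. Of 10 regulators of ribosomal genes IFH1 (4.61-fold) and TOD6 (3.13-fold) rose and 2 fell at 10 min, CRF1 2.67-fold, with the same counts when adjusted over the list alone (median -0.31 as deposited, positive under another scaling, adjusted p = 0.89).

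Beyond the genes that prompted each question, 3 hypotheses were tested. Leu3 target genes other than those named above may be lower in the deletion strain at steady state: over 7 genes the median was -0.358 and none passed (camera p = 0.35 with an estimated correlation), which leaves it open. Aft1 targets of iron uptake may have a negative interaction at 60 min like FET4: over 9 genes the median was -0.226 (camera p = 0.014 with an estimated correlation). ARN1 lay at -1.46 and FTR1 at -1.29 but FRE1 at 1.47, and no single gene passed. The test sets the list against the other genes and was run as deposited only. The median interaction over all genes was then 0.26, but 0.00 after quantile normalization and -0.08 with a common median. The p therefore does not by itself show a negative interaction. Pheromone-induced genes may be higher at steady state beyond FUS1 and PRM1: over 16 genes the median was 0.644 with 5 called higher (AGA2 1.12, FIG2 1.22, KAR4 0.95, PRM2 1.16 and PRM5 1.17), while the list missed the threshold (p = 0.065 with an estimated correlation).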
